A study of Mus musculus with 25 samples.

How the data were processed

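RNA was sequenced from 25 biopsies of tumors that the mouse melanoma line YUMM1.7 formed in C57BL/6 mice. YUMM1.7 carries mutant Braf. Per the labels, RNA was extracted with a mirVana kit, poly(A) RNA was made into unstranded TruSeq libraries, and paired reads of 100 bases were sequenced on an Illumina HiSeq instrument. The labels give 7 groups. The untreated tumors (Veh, n = 4), the tumors regressing on a BRAF inhibitor (Reg, n = 4), the residual tumors (Res, n = 5) and the resistant tumors (Prog, n = 5) form batch 1. A second set of resistant tumors (Prog_b2, n = 3) and the small (aPDL2_small, n = 2) and large (aPDL2_large, n = 2) tumors on the inhibitor with an antibody against PD-L2 form batch 2. The inhibitor's name is not given in the sources used here. The labels count tumors within a group, and nothing in them says whether these came from separate mice. The p-values of single genes therefore measure the spread between these samples.

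The authors' deposited table holds FPKM (fragment counts scaled by transcript length and library size) for 23940 gene symbols in the 25 libraries. Per the submitters' processing notes, reads were mapped to mm9 with TopHat or TopHat2, and Cuffnorm and Cuffdiff were used; their versions and their separate roles are not given in the sources used here. The values had been scaled across libraries, since the sums of the columns ranged from 496435 to 2065749 while size factors by the median of ratios lay between 0.942 and 1.059. In 9 columns of batch 1 (Veh 1, 2 and 4, Res 1, 3 and 5, and Prog 2, 4 and 5) many values ended in a seventh digit, as the mean of a pair of values would; the other 16 columns held single values. No read counts were used here, so the depth behind each value is unknown and no counting interval is given. In the 16 columns with single values, the step that 1 fragment makes in genes of low expression spanned 1.79-fold. Of the symbols, 22375 matched a current RefSeq symbol and 1427 an older synonym, and 138 matched neither. The order of genes on chromosomes came from the RefSeq annotation of GRCm38.p6.

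FPKM were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 1 term per group and a variance trend over expression (lmFit, contrasts.fit and eBayes). Genes with a mean FPKM of at least 1 over the libraries of a fit were tested. Tests were two-sided, and a gene was called when its p, adjusted by Benjamini and Hochberg over all genes tested, was below 0.05. Comparisons within batch 1 came from a fit of its 18 libraries and comparisons within batch 2 from a fit of its 7. The comparison of resistant tumors between batches, and the difference between the residual-to-resistant contrasts of the batches, came from a fit of all 25. Fixed gene lists, 39 in all, were tested with limma's camera with a preset correlation between genes of 0.01 where at least 3 members were tested, with adjustment over the lists of a comparison. Camera compares a list's genes with all other genes, so with this preset its p-values do not measure how a list's mean varies between tumors. Members of each list were also counted with p adjusted over the list alone. Unless stated otherwise, adjusted p-values are limma's, FPKM are means ± SD, and log2 changes are given ± SE. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

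The comparisons, the lists, the rule for named genes and the other settings first chosen were fixed before the data were examined. For Reg, Res and Prog against Veh, the rule takes the 10 called genes with the largest rise and the 10 with the largest fall whose libraries did not overlap between the groups, and for the other comparisons 5 and 5. Predicted genes, RIKEN and LOC symbols, microRNAs, small nucleolar RNAs and segments of immunoglobulin and T cell receptor genes are left out of these. Up to 4 members per list with the smallest adjusted p, and always Dusp6, Spry4, Mki67, Mitf, Dct, Axl, Pdgfrb, Adgre1 (Emr1 in the table), Cd8a, Cd274 and Pdcd1lg2 where measured, are added. Dct, near 0 in all groups, was tested in no fit, and Pdcd1lg2 passed the expression filter in batch 2 alone. A few genes that the rule takes are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

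The other settings were a pseudocount of 0.1, no filter beyond a mean above 0, median-of-ratios size factors, the replicate number as a block, library weights, a fit of all libraries or of the compared groups alone, the resistant tumors of batch 2 in place of or joined to those of batch 1, camera with an estimated correlation, fry, and each library left out in turn. Chosen after seeing the data were a term for the columns that look like means, the fits without the 3 libraries with high keratin, and an exact permutation of list means per library. Each comparison was also tested on simulated data with 200 genes changed. The changed genes had a mean FPKM of at least 4, and noise was drawn independently for each gene. The shares recovered therefore do not carry over to weaker genes or to genes that vary together between tumors. Changes of 2-fold were recovered for 77.6 to 88.1% of genes in the comparisons of batch 1, for 79.1% in Prog_b2 against Prog and for 50.7% in the difference between the contrasts. In the 3 comparisons within batch 2 this share was 9 or 6%, and changes of 4-fold were recovered for 45.5 to 60.6%.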

Results

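The series followed YUMM1.7 melanomas before treatment and on MAPK pathway inhibition, and asked how the transcriptome differed between untreated, regressing, residual and resistant tumors, and in tumors also given anti-PD-L2. FPKM were measured for 25 tumors in 7 groups, 18 in batch 1 and 7 in batch 2. Between 11081 and 12262 genes per library had at least 1 FPKM. The first principal component held 41.3% of the variance and the second 11.1%. No pair of libraries was a duplicate, with a highest rank correlation across genes of 0.981. The transcript Mir2137 alone held between 0 and 66.1% of a library's FPKM sum.

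Some libraries stood apart in markers of skin or muscle. Krt14, a keratin of basal keratinocytes, was at 592 FPKM in Veh 1, 98.2 in Veh 3 and 158 in Res 1. Acta1, the actin of skeletal muscle, ranged from 132 to 296 FPKM in Res 2 to Res 5 and was at 21.3 in Res 1. The mean Acta1 level was 13.7 ± 11.7 FPKM in Veh (n = 4) and 163 ± 103 in Res (n = 5).

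**Figure D1:**
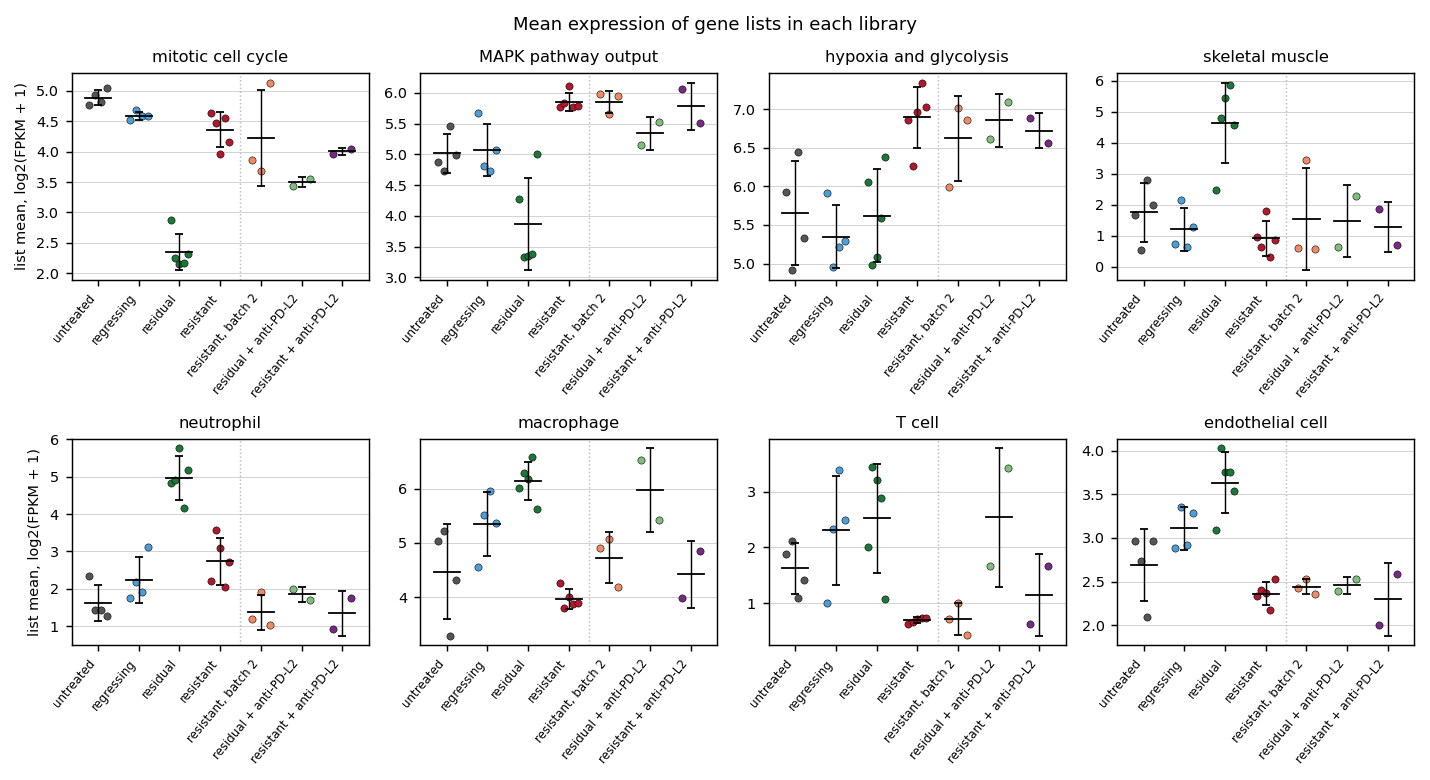
Mean log2(FPKM + 1) of 8 fixed gene lists (y axis) in each library (points) by group (x axis), with the group mean (line) and SD (bars); a dotted line parts batch 1 from batch 2. The mitotic and MAPK output lists were lowest in Res, where their median log2 changes against Veh were -2.55 and -1.16, and the neutrophil list was highest there.

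Regressing tumors were compared with untreated tumors to ask what changed while tumors shrank on the inhibitor. The mean of the MAPK output list did not move measurably at this stage, at 5.07 in Reg and 5.02 in Veh on the log2 scale. The difference was 0.057 (exact permutation p = 0.771, a test chosen after seeing the data). Dusp6, the ERK phosphatase that ERK signalling induces, stood at 114 ± 16.3 FPKM in Reg and 98.8 ± 17.5 in Veh (n = 4 each; log2 change 0.22 ± 0.24, adjusted p = 0.739). Spry4, another feedback inhibitor of the pathway, had a log2 change of 0.34 (adjusted p = 0.652), and the proliferation marker Mki67 one of -0.33 (adjusted p = 0.484). Lars2, a mitochondrial leucyl-tRNA synthetase, fell from 711 ± 182 to 125 ± 47.0 FPKM (log2 change -2.53 ± 0.28, adjusted p = 0.000687). With only the Reg and Veh libraries in the fit, its adjusted p was 0.0511, and the 2 genes then called shared 0 with the 2 called here. The share of Mir2137 in the FPKM sum also separated these groups, at 0 to 16.8% in Reg and 32.8 to 66.1% in Veh. The only other called gene was the microRNA Mir6236, which lies outside the rule for named genes and was chosen after its values were seen (log2 change -2.84, adjusted p = 0.000575).

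Immune lists stood higher in Reg as groups, although no member passed the test over all genes. By exact permutation of list means per library 0 lists passed here after adjustment. The unadjusted exact p was 0.143 for the macrophage list and 0.0286 for the mitotic list. Of 15 macrophage genes 3 rose with p adjusted over the list alone, and the list's median log2 change was 0.96 (camera adjusted p = 1.32e-06; adjusted p = 0.526 with an estimated correlation). Emr1, the macrophage marker F4/80, had a log2 change of 1.13 (adjusted p = 0.477). The 8 mast cell genes had a median of 2.17 (adjusted p = 0.000163; adjusted p = 0.526 with an estimated correlation) and the 13 cytotoxic lymphocyte genes one of 0.93 (adjusted p = 0.00254; adjusted p = 0.677 with an estimated correlation, 0.259 without Reg 3 and 0.0671 without Veh 3). None of these 21 genes passed when adjusted over the list alone. Among them Cd8a, the coreceptor of killer T cells, had a log2 change of 1.12 (adjusted p = 0.486). The 14 checkpoint receptors and ligands had a median of 0.82, with 0 called when adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.526 with an estimated correlation). Cd274, which encodes PD-L1, had a log2 change of 0.97 (adjusted p = 0.473). The 23 mitotic genes had a median of -0.30, with 0 called when adjusted over the list alone (adjusted p = 5.39e-07; adjusted p = 0.526 with an estimated correlation). Mitf, the master regulator of melanocytes, and the receptor tyrosine kinases Axl and Pdgfrb did not pass either, with log2 changes of 0.35, 0.03 and 0.02.

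Between Reg and Veh, limma called 2 of 12210 genes, both lower, and 1364 had an unadjusted p below 0.05. The count was 31 with library weights, and camera called 20 lists against 9 without Veh 3 and 0 by fry or with an estimated correlation.

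Residual tumors were compared with untreated tumors to describe tumors that persisted on the inhibitor without growing. Saa3, an acute-phase serum amyloid, rose from 18.9 ± 7.89 FPKM in Veh (n = 4) to 1033 ± 559 in Res (n = 5; log2 change 5.45 ± 0.65, adjusted p = 7.93e-06). Haptoglobin (Hp) rose by a log2 change of 5.31 ± 0.82 (adjusted p = 0.000104). S100a9 and S100a8, the subunits of calprotectin in neutrophils, rose by 5.03 ± 0.84 and 4.54 ± 0.81. The neutrophil-attracting chemokines Cxcl1 and Cxcl5 rose by 4.91 and 4.31, the iron-binding lipocalin Lcn2 by 4.14, the mast cell chymase Cma1 by 3.86, and Retnlg and the stefin Stfa2l1 by 3.72 each.

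Ccnb1, the cyclin that drives entry into mitosis, fell from 41.3 ± 3.84 to 4.43 ± 1.36 FPKM (log2 change -2.99 ± 0.16, adjusted p = 2.68e-09). Ube2c of the anaphase-promoting complex (-2.95), Fam64a (-2.92), the polo-like kinase Plk1 (-2.90), the mitotic kinase Pbk (-2.88), the cytokinesis protein Anln (-2.86) and the topoisomerase Top2a (-2.83) fell alongside it. All 23 mitotic genes fell, over all genes and when adjusted over the list alone, with a median of -2.55 (camera adjusted p = 1.22e-22; adjusted p = 0.172 with an estimated correlation). Mki67 fell from 27.4 ± 1.02 to 4.36 ± 1.42 FPKM (-2.44 ± 0.17, adjusted p = 1.74e-08). Of 20 DNA replication genes 19 fell, the same number when adjusted over the list alone (median -1.76, camera adjusted p = 3.11e-17; adjusted p = 0.172 with an estimated correlation). The helicase subunit Mcm6 fell from 60.1 ± 6.89 to 12.1 ± 1.66 FPKM. The largest falls also held the neuronal pentraxin Nptx1 (-4.11 ± 0.52) and the neurofilament gene Nefl (-2.94).

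MAPK output fell in the residual tumors. Of 21 genes 17 fell and 4 did not pass, also when adjusted over the list alone (median -1.16, camera adjusted p = 3.85e-05; adjusted p = 0.513 with an estimated correlation). Ccnd1, the G1 cyclin downstream of ERK, fell from 310 to 52.5 ± 30.7 FPKM (-2.71 ± 0.29, adjusted p = 2.37e-06). Spry4 fell by 2.18 on the log2 scale (adjusted p = 1.7e-05) and Dusp6 from 98.8 ± 17.5 to 38.2 ± 20.3 FPKM (-1.45 ± 0.23, adjusted p = 0.00014). In the melanocyte lineage 4 of 7 genes rose and 2 fell, counts that were the same when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.534). Mitf rose from 3.17 ± 1.06 to 7.29 ± 2.42 FPKM (0.98 ± 0.25, adjusted p = 0.00464), whereas the receptor gene Met fell (-1.38 ± 0.23, adjusted p = 0.000175). Axl did not pass (-0.32, adjusted p = 0.054).

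Markers of infiltrating and stromal cells rose in Res. All 11 neutrophil genes rose, also when adjusted over the list alone, among them the lectin receptor Clec4d (3.66 ± 0.27) and the chemokine receptor Cxcr2 (2.39 ± 0.23). Their median was 3.17 (camera adjusted p = 1.91e-07; adjusted p = 0.172 with an estimated correlation). Of 15 macrophage genes 14 rose, also when adjusted over the list alone (median 1.77, camera adjusted p = 1.28e-05; adjusted p = 0.443 with an estimated correlation). They include the lipopolysaccharide coreceptor Cd14 (2.22 ± 0.32) and the lysosomal Cd68 (2.78 ± 0.46). Of 16 myeloid chemokines 13 rose and 1 fell, also when adjusted over the list alone (median 2.39, camera adjusted p = 0.000185; adjusted p = 0.302 with an estimated correlation), with the monocyte attractant Ccl8 going from 162 ± 66.2 to 1281 ± 485 FPKM. Of 14 endothelial genes 13 rose, also when adjusted over the list alone, the junction protein Esam by 1.30 ± 0.23 (median 1.06, camera adjusted p = 3.85e-05; adjusted p = 0.443 with an estimated correlation). Of 16 fibroblast genes 11 rose, also when adjusted over the list alone (median 0.90, camera adjusted p = 0.00035; adjusted p = 0.259 with an estimated correlation). The matrix genes Dpt (3.38 ± 0.37) and Postn (2.46 ± 0.41) were among them.

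Of 12 T cell genes 1 rose, Cd4, by 1.92 ± 0.46, also when adjusted over the list alone (median 0.95, camera adjusted p = 0.0281; adjusted p = 0.704 with an estimated correlation, 0.0812 without Res 2, 0.0719 without Res 3 and 0.0965 without Veh 3). Of 13 cytotoxic lymphocyte genes 1 rose, Ccl5, by 1.88 (adjusted p = 0.0429, and from 0.0965 to 0.123 without any 1 of 5 single libraries), and 0 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0766). Cd8a had a log2 change of 1.06 (adjusted p = 0.15). The B cell receptor regulator Cd22 rose by 1.87 (adjusted p = 0.00088). None of the 18 interferon gamma response genes passed, over all genes or when adjusted over the list alone (median 0.55, camera adjusted p = 0.195). Of the 14 checkpoint genes 5 rose, also when adjusted over the list alone (median 1.14, camera adjusted p = 0.00383; adjusted p = 0.546 with an estimated correlation), among them the inhibitory receptor Cd200r1 (1.27, adjusted p = 0.00184). Cd274 passed at a log2 change of 1.38 (adjusted p = 0.0304), but its adjusted p was 0.0765 without Res 4, 0.0877 without Veh 3 and 0.102 without Veh 4. Emr1 rose by 1.90 (adjusted p = 0.0132), with an adjusted p of 0.0527 without Veh 3. Pdgfrb rose by 0.35 (adjusted p = 0.0165), with an adjusted p of 0.0736 without Veh 4, 0.06 with library weights and 0.246 with all 25 libraries in 1 fit.

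Other tissues moved with this group. All 11 skeletal muscle genes rose in Res, also when adjusted over the list alone (median 3.08, camera adjusted p = 1.53e-05; adjusted p = 0.46 with an estimated correlation), and 7 of 8 erythroid genes rose, also when adjusted over the list alone (median 3.17, adjusted p = 0.00133; adjusted p = 0.426 with an estimated correlation). The myosin Myh1 rose from 0.594 ± 0.228 to 25.5 ± 18.2 FPKM and Alas2, the first enzyme of haem synthesis in red cells, from 2.97 ± 0.324 to 38.9 ± 24.1 FPKM.

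In all, 5560 of 12210 genes passed between Res and Veh, 2492 higher and 3068 lower, and 6489 had an unadjusted p below 0.05. Without the libraries with high Krt14 (Veh 1, Veh 3 and Res 1), a choice made after the values were seen, 4106 passed. With size factors 50.5% of the called genes were higher, against 44.8%.

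**Figure D2:**
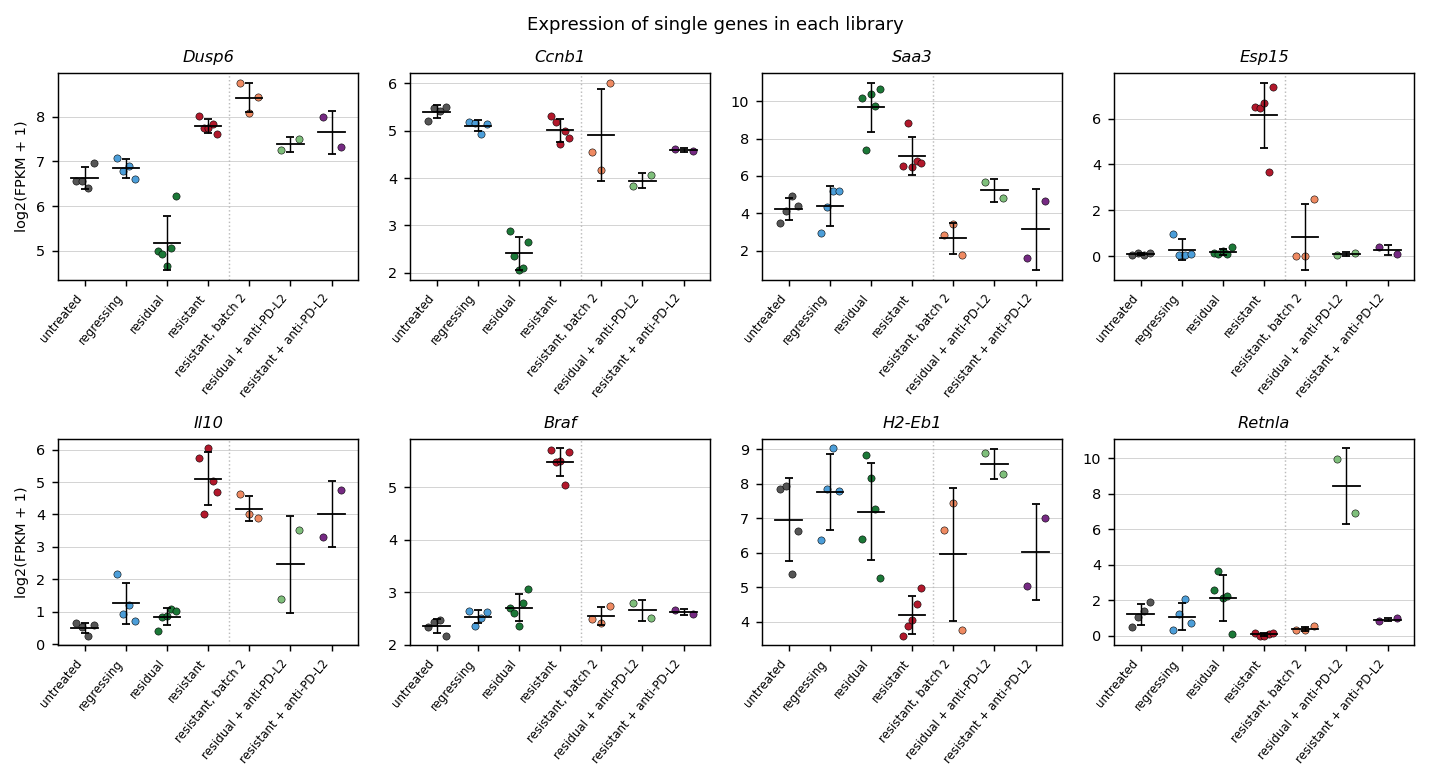
Log2(FPKM + 1) of 8 genes (y axis) in each library (points) by group (x axis), with the mean (line) and SD (bars) of the log values; a dotted line parts the batches. Dusp6 and Ccnb1 were lowest in Res, Saa3 was highest in Res, and Esp15 and Braf were highest in Prog of batch 1.

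Resistant tumors of batch 1 were compared with untreated tumors to describe growth under the inhibitor. Esp15, a secreted exocrine gland peptide, rose from 0.0761 to 91.0 ± 54.4 FPKM (Veh n = 4, Prog n = 5; log2 change 6.03 ± 0.50, adjusted p = 7.95e-07), and bone sialoprotein (Ibsp) rose by 6.03 as well. The immunosuppressive cytokine Il10 rose from 0.419 ± 0.154 to 37.9 ± 20.6 FPKM (4.61 ± 0.35, adjusted p = 4.75e-07). The EGF receptor ligand Areg rose by 4.63 ± 0.85, the keratin Krt20 by 5.20, the prolactin family members Prl8a9 and Prl2c3 by 5.07 and 4.64, the imprinted gene Phlda2 by 4.79, the natriuretic peptide Nppb by 4.66 and the collagenase Mmp1b by 4.45. With the resistant tumors of batch 2 in place of batch 1, Krt20, Prl2c3 and Nppb no longer passed (adjusted p = 0.396, 0.387 and 0.149), and Esp15, Prl8a9 and Phlda2 were below the expression filter.

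Among the largest falls, Cx3cr1, the fractalkine receptor of monocytes and macrophages, fell from 19.4 ± 11.1 to 0.171 ± 0.153 FPKM (-3.90 ± 0.42, adjusted p = 8.9e-06). Its ligand Cx3cl1 fell too (-2.16 ± 0.30). The lysosomal nuclease Pld4 (-2.94), the lymphocyte antigen Ly86 (-2.80), the class II gene H2-Eb1 (-2.76 ± 0.69), the interferon-induced Ifi27l2a (-2.71) and the macrophage lectin Mgl2 (-2.61) fell, as did proenkephalin (Penk, -3.76), the matrix protein Spon2 (-3.43), the creatine synthesis enzyme Gatm (-2.64) and the granzyme Gzmc (-2.49; adjusted p = 0.0121, and 0.0504 without Veh 1). With the resistant tumors of batch 2 in place, of these genes only Spon2 still passed (adjusted p = 0.00794). H2-Eb1 then had an adjusted p of 0.507. Cx3cr1 was at -0.78, Gatm at -0.80, Gzmc at -0.58, Pld4 at -0.42, Mgl2 at -0.39, Ly86 at -0.12 and Penk at -0.11, with adjusted p from 0.27 to 0.926, and Cx3cl1 (adjusted p = 0.0639) and Ifi27l2a (adjusted p = 0.423) did not pass either.

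Of 21 MAPK output genes 9 rose, 1 fell and 11 did not pass, also when adjusted over the list alone (median 0.83, camera adjusted p = 0.0377; adjusted p = 0.919 with an estimated correlation). Dusp6 rose from 98.8 ± 17.5 to 221 ± 23.4 FPKM (1.16 ± 0.23, adjusted p = 0.000926), Spry4 by 1.13 (adjusted p = 0.0039) and the phosphatase Dusp4 by 3.43 ± 0.51. The member that fell was Spry1 (-1.78 ± 0.31; adjusted p = 0.0715 with the resistant tumors of batch 2 in place). Of 23 mitotic genes 15 fell, 16 when adjusted over the list alone (median -0.54, camera adjusted p = 0.000361; adjusted p = 0.919 with an estimated correlation). Mki67 fell by 0.68 on the log2 scale (adjusted p = 0.0043, and 0.0824 with those of batch 2). Of 20 DNA replication genes 11 fell and 1 rose, also when adjusted over the list alone (median -0.36, camera adjusted p = 0.0146; adjusted p = 0.919 with an estimated correlation).

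Of 19 genes of hypoxia and glycolysis 15 rose, 16 when adjusted over the list alone (median 1.24, camera adjusted p = 0.000577; adjusted p = 0.919 with an estimated correlation), among them the stress gene Ndrg1 (2.49 ± 0.35; adjusted p = 0.0899 with those of batch 2) and hexokinase Hk2 (1.43 ± 0.30). Of 18 angiogenesis and wound healing genes 10 rose and 2 fell, 11 and 2 when adjusted over the list alone (median 1.11, camera adjusted p = 0.0377; adjusted p = 0.919 with an estimated correlation, 0.0514 without Prog 1 and 0.0532 without Veh 4). The urokinase gene Plau rose from 110 ± 115 to 1271 ± 116 FPKM (4.07 ± 0.58). Of 20 mesenchymal transition genes 11 rose and 2 fell, 12 and 2 when adjusted over the list alone (median 0.75, camera adjusted p = 0.0377; adjusted p = 0.919 with an estimated correlation and 0.0564 without Veh 4). Tgfb1 rose by 1.44 (adjusted p = 1.86e-05) and the transcription factor Snai2 fell (-0.80; adjusted p = 0.0537 with those of batch 2). The platelet-derived growth factor receptor Pdgfrb rose from 61.0 ± 7.67 to 120 ± 14.7 FPKM (0.97 ± 0.11, adjusted p = 1.27e-05, and 0.144 with those of batch 2), and the EGF receptor ligand Hbegf by 2.79 ± 0.47. Axl and Mitf did not pass (-0.13 and 0.35).

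Of 9 MHC class II genes 6 fell, 8 when adjusted over the list alone (median -1.55, camera adjusted p = 0.0241; adjusted p = 0.919 with an estimated correlation). Of 18 interferon gamma response genes 6 fell, 5 when adjusted over the list alone (median -1.30, camera adjusted p = 0.00692; adjusted p = 0.919 with an estimated correlation). The immunoproteasome subunit Psmb9 (-2.07 ± 0.55) and the class II chaperone Cd74 (-2.23 ± 0.65) were among them. Of 14 endothelial genes 9 fell and 2 rose, also when adjusted over the list alone (median -0.77, camera adjusted p = 0.0385; adjusted p = 0.919 with an estimated correlation). That list was not called with size factors (0.0653) or without Prog 3, Prog 4, Veh 1, Veh 2 or Veh 4 (0.0512, 0.0628, 0.0874, 0.0529 and 0.0898). Sox18 fell (-1.27 ± 0.24), while the cadherin Cdh5 and the VEGF receptor Flt1 rose by 2.80 ± 0.28 and 2.38 ± 0.34. Of 15 macrophage genes 7 fell and 2 rose, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.255). Lyz2 fell (-2.21 ± 0.48). With the resistant tumors of batch 2 in place, Cd74 (-0.87, adjusted p = 0.564), Psmb9 (-1.27, 0.288), Sox18 (-0.48, 0.283), Cdh5 (0.80, 0.211) and Lyz2 (-0.25, 0.797) no longer passed. Emr1 passed at -1.53 (adjusted p = 0.0391), but not without any 1 of 8 single libraries, all but Veh 3, where its adjusted p ranged from 0.0513 to 0.149. Cd8a (-1.08, adjusted p = 0.14) and Cd274 (1.03, adjusted p = 0.0958) did not pass. The checkpoint ligands Cd276 and Cd80 rose by 1.41 ± 0.18 and 1.84 ± 0.36, and 2 of 14 checkpoint genes rose and 1 fell, 2 and 0 when adjusted over the list alone.

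Between Prog and Veh, 5658 genes passed, 3082 higher and 2576 lower, and 6595 had an unadjusted p below 0.05. With the 3 resistant tumors of batch 2 in place of the 5 of batch 1, 2014 passed, 890 higher and 1124 lower, of which 1628 were also called with batch 1 and 1614 in the same direction. Of the 80 called genes that the rule names here or that were added and that were tested again, 29 still passed in that setting, 45 did not and 6 turned direction; Esp15, Prl8a9 and Phlda2 were not tested there. With size factors 49.6% of the called genes were higher, against 54.5%.

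Braf itself, chosen after its values were seen, was higher in Prog of batch 1 than in all other tumors. It stood at 44.2 ± 7.62 FPKM in Prog (n = 5) and 4.13 ± 0.452 in Veh (n = 4; log2 change 3.12 ± 0.14, adjusted p = 1.47e-09), and at 4.87 ± 0.722 in Prog_b2 (n = 3). In single tumors it ranged from 31.9 to 51.3 FPKM in Prog and from 3.52 to 7.35 in the other 20. Its neighbours on chromosome 6 (order from GRCm38.p6), also chosen after their values were seen, rose with it. Kdm7a, Mrps33, Slc37a3 and Hipk2 had log2 changes of 3.08, 2.99, 2.69 and 2.37. Of 26 tested genes from Creb3l2 to Ephb6, 21 were higher in Prog than in Veh, while Tbxas1 was lower (-1.47).

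**Figure D3:**
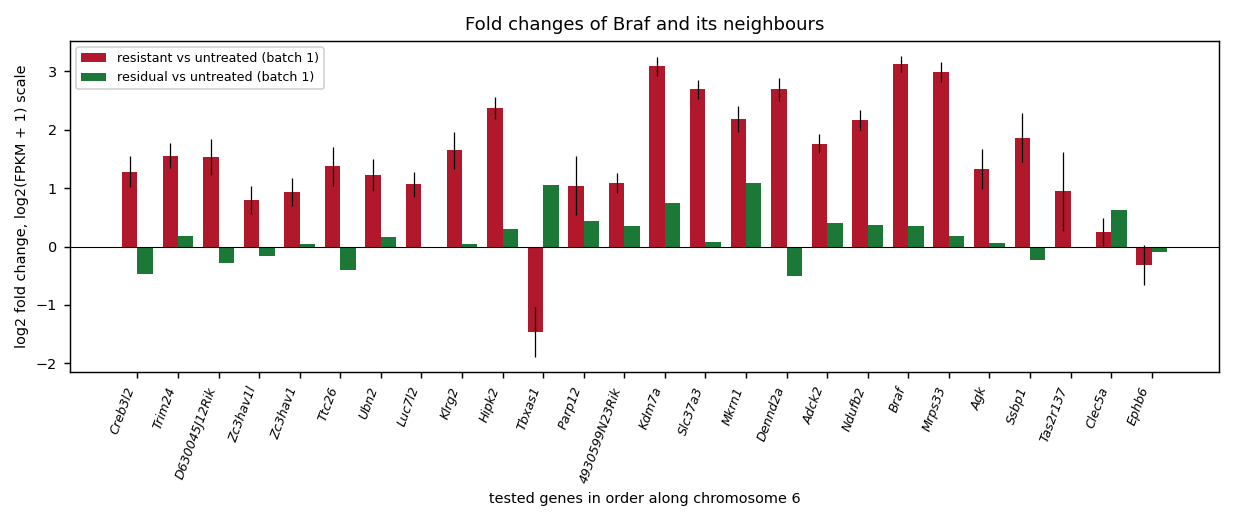
Log2 change against Veh (y axis) of 26 tested genes in their order on chromosome 6 from Creb3l2 to Ephb6 (x axis), for Prog (red bars with SE) and Res (green bars). Braf and its neighbours rise in Prog, Braf by 3.12, while in Res Braf changed by 0.35 and the genes shown ranged from -0.50 (Dennd2a) to 1.09 (Mkrn1).

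Residual tumors were compared with regressing tumors to ask what separated these stages on the inhibitor. The largest named rises in Res were beta globin Hbb-bs at 5.61 ± 1.42, Saa3 at 5.27 ± 0.65, S100a9 at 4.97, Hp at 4.77 and alpha globin Hba-a2 at 4.55 (Res n = 5, Reg n = 4). Nptx1 (adjusted p = 0.000399), Anln (-2.75 ± 0.18), Ccnb1 (-2.70 ± 0.16, adjusted p = 1.55e-08), the cell cycle repressor E2f8 (-2.65) and Plk1 (-2.60) fell most. All 23 mitotic genes fell, also when adjusted over the list alone (median -2.18, camera adjusted p = 1.53e-24; adjusted p = 0.149 with an estimated correlation). Mki67 fell by 2.11 on the log2 scale (adjusted p = 1.45e-07). Of 21 MAPK output genes 16 fell, 17 when adjusted over the list alone (median -1.19, camera adjusted p = 4.83e-06; adjusted p = 0.565 with an estimated correlation), with Dusp6 at -1.67 ± 0.23 and Spry4 at -2.52 ± 0.28.

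Neutrophil and stromal markers separated these stages too. Of 11 neutrophil genes 10 rose in Res, 11 when adjusted over the list alone (median 2.37, camera adjusted p = 1.43e-07; adjusted p = 0.149 with an estimated correlation). Of 16 fibroblast genes 9 rose, also when adjusted over the list alone, Dpt by 3.19 ± 0.37 (median 0.89, camera adjusted p = 9.08e-05; adjusted p = 0.204 with an estimated correlation). In the macrophage list 5 of 15 genes rose, 4 when adjusted over the list alone (median 0.72, camera adjusted p = 0.00638; adjusted p = 0.753 with an estimated correlation and 0.0511 without Reg 1). All 11 muscle genes rose, also when adjusted over the list alone (median 3.67, camera adjusted p = 2.06e-08; adjusted p = 0.35 with an estimated correlation). Emr1 (0.77, adjusted p = 0.312), Cd8a (-0.06, adjusted p = 0.948), Cd274 (0.40, adjusted p = 0.551) and Mitf (0.64, adjusted p = 0.0556) did not pass. Axl passed at -0.35 (adjusted p = 0.0452), but not without any 1 of 7 of the 9 libraries, where its adjusted p ranged from 0.051 to 0.131, nor with size factors (0.095) or no filter (0.0598). Pdgfrb passed at 0.32 (adjusted p = 0.0281), but not without Res 1, Reg 1 or Reg 3 (0.07, 0.0554 and 0.0819), with library weights (0.0901) or with all 25 libraries in 1 fit (0.309).

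Of 12210 genes, 4443 passed between Res and Reg, 1701 higher (38.3%) and 2742 lower, and 5602 had an unadjusted p below 0.05. With median-of-ratios size factors 48.5% of the called genes were higher.

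Resistant tumors of batch 1 were compared with residual tumors to ask what marked regrowth. Nefl rose from 1.80 to 175 FPKM (6.10 ± 0.61, adjusted p = 4.77e-07), Esp15 by 5.95, Ibsp by 5.81, Prl8a9 by 5.33 and Plau by 5.26 ± 0.55 (n = 5 each). Hba-a2 (-6.00 ± 0.85), the mast cell proteases Cma1 (-4.73) and Tpsb2 (-4.68) and Acta1 (-4.66) fell, and the lipid carrier Apoe fell from 7975 ± 3659 to 238 ± 50.7 FPKM (-4.94 ± 0.49, adjusted p = 4.33e-07). Of 21 MAPK output genes 18 rose, also when adjusted over the list alone, Spry4 by 3.31 ± 0.26 and Dusp6 by 2.62 ± 0.22 (median 2.25, camera adjusted p = 7.65e-05; adjusted p = 0.634 with an estimated correlation). All 23 mitotic genes rose, also when adjusted over the list alone, Ccnb1 by 2.60 ± 0.15 and Mki67 by 1.76 (median 1.86, camera adjusted p = 2.32e-10; adjusted p = 0.634 with an estimated correlation). Of 19 hypoxia and glycolysis genes 16 rose, also when adjusted over the list alone (median 1.25, camera adjusted p = 0.00699; adjusted p = 0.634 with an estimated correlation).

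Immune lists fell from Res to Prog. Of 12 T cell genes 11 fell, also when adjusted over the list alone, Cd4 by 3.39 on the log2 scale (median -2.03, camera adjusted p = 0.00286; adjusted p = 0.634 with an estimated correlation). Of 13 cytotoxic lymphocyte genes 9 fell, also when adjusted over the list alone, with Cd8a at -2.13 (adjusted p = 0.00247; list median -1.77, camera adjusted p = 0.0139; adjusted p = 0.634 with an estimated correlation). Of 15 macrophage genes 11 fell, also when adjusted over the list alone, with Lyz2 at -4.12 ± 0.45 and Emr1 at -3.43 (list median -3.09, camera adjusted p = 0.000244; adjusted p = 0.634 with an estimated correlation). Of 18 interferon gamma response genes 15 fell, 17 when adjusted over the list alone (median -1.73, camera adjusted p = 0.0014; adjusted p = 0.634 with an estimated correlation). Of 14 endothelial genes 12 fell and 2 rose, also when adjusted over the list alone (median -1.77, camera adjusted p = 0.000412; adjusted p = 0.634 with an estimated correlation). All 11 muscle genes fell as well, also when adjusted over the list alone (median -4.09, camera adjusted p = 0.000104; adjusted p = 0.634 with an estimated correlation). Cd274 (-0.35, adjusted p = 0.502) and Axl (0.19, adjusted p = 0.168) did not pass, and Pdgfrb rose by 0.62 ± 0.10.

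Of 12210 genes, 8839 passed between Prog and Res, 4879 higher and 3960 lower, and 9085 had an unadjusted p below 0.05. With size factors 49.8% of the called genes were higher, against 55.2%. Mitf fell (-0.64, adjusted p = 0.0228), but its adjusted p was 0.0672 without Prog 2, 0.0593 without Prog 5, 0.0591 without Res 2 and 0.0686 without Res 4.

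The calls of the residual and resistant states of batch 1 against Veh were compared. Called in both were 432 genes higher in each and 647 lower in each, where independent calls would give 629 and 647, and 1399 genes went in opposite directions, where independent calls would give 1300. Both comparisons use the same Veh libraries, so their calls are not independent. Simulated unchanged groups that shared a set of redrawn Veh libraries gave a mean of 26.86 and at most 1543 genes called in the same direction, against 1079 here. Across genes, which are not independent replicates, the log2 changes correlated at r = -0.041. The simulated groups gave a mean r of 0.576 ± 0.224 (SD, 100 simulations). With separate Veh libraries for each, in 6 splits, r ranged from -0.28 to 0.083. For Reg and Res r was 0.542 against a simulated 0.541, and from 0.173 to 0.41 with separate Veh libraries. For Reg and Prog r was 0.163 against 0.548, and from -0.244 to 0.357. The simulated groups held no change, while r divides the covariance by a spread that real changes widen, so these r values are not alike. The covariance for Reg and Res was 0.152 against a simulated 0.049 ± 0.043 (SD), and from 0.069 to 0.127 with separate Veh libraries. For Res and Prog it was -0.022 against 0.051 ± 0.045 (from -0.201 to 0.04). For Reg and Prog it was 0.045 against 0.052 ± 0.043 (from -0.11 to 0.084).

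Small residual tumors on the inhibitor with anti-PD-L2 were compared with the resistant tumors of the same batch, to ask how they differed. Batch 2 holds no small tumors on the inhibitor alone, so the antibody and the small state cannot be told apart here. No gene passed over all genes, so values are given without a call. Retnla, a product of macrophages activated by type 2 cytokines, was at 562 ± 622 FPKM in aPDL2_small (n = 2) and 0.302 ± 0.120 in Prog_b2 (n = 3; log2 change 8.08 ± 0.79, adjusted p = 0.109). Of 16 genes of alternative macrophage activation 7 rose when adjusted over the list alone (median 2.05, camera adjusted p = 9.61e-09; adjusted p = 0.446 with an estimated correlation). The chemokine Ccl22 was at 3.58 ± 0.47 and the folate receptor Folr2 at 3.10 ± 0.44. All 7 mast cell genes rose when adjusted over the list alone, with the chymases Cma1 and Mcpt4 at 3.73 ± 0.41 and 3.54 ± 0.37 (list median 3.46, camera adjusted p = 5.81e-13; adjusted p = 0.446 with an estimated correlation, and 0.0368 by fry). Of 10 T cell genes 6 rose when adjusted over the list alone, with the adhesion receptor Cd2 at 3.11 ± 0.63 (list median 2.29, camera adjusted p = 1.33e-07; adjusted p = 0.446 with an estimated correlation).

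Fat and nerve markers moved with this group. All 10 adipocyte genes rose when adjusted over the list alone, with the lipase Lipe at 2.47 ± 0.40 (list median 3.64, camera adjusted p = 1.65e-09; adjusted p = 0.446 with an estimated correlation). Of 9 Schwann cell and nerve genes 4 rose when adjusted over the list alone, with myelin basic protein Mbp at 2.56 ± 0.37 (list median 1.74, camera adjusted p = 2.34e-05; adjusted p = 0.446 with an estimated correlation). The 23 mitotic genes had a median of -0.72 and the 21 MAPK output genes one of -0.55, with 0 called in either when adjusted over the list alone (camera adjusted p = 2.08e-05 and 0.000683; adjusted p = 0.504 and 0.446 with an estimated correlation, and 0.0899 for MAPK output without aPDL2_small 1). Dusp6 (-1.05, adjusted p = 0.284), Mki67 (-0.50, adjusted p = 0.698), Emr1 (1.60, adjusted p = 0.282), Cd8a (2.19, adjusted p = 0.423), Pdgfrb (-1.31, adjusted p = 0.412) and Pdcd1lg2, which encodes PD-L2 (0.36, adjusted p = 0.716), did not pass.

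For aPDL2_small against Prog_b2, limma called 0 of 11913 genes, with 1399 at an unadjusted p below 0.05 and a smallest adjusted p of 0.109. The count was 598 with all 25 libraries in 1 fit and 16 without aPDL2_small 2, which left a lone library assumed to vary like the other groups.

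Large resistant tumors on the combination were compared with Prog_b2 to ask what anti-PD-L2 left changed in tumors that grew. Dusp6 was at 206 ± 68.2 FPKM in aPDL2_large (n = 2) and 350 ± 79.8 in Prog_b2 (n = 3; log2 change -0.78), and Emr1 had a log2 change of -0.87, both with an adjusted p of 1. The 10 adipocyte genes had a median of 1.03 (camera adjusted p = 1.86e-05; adjusted p = 0.839 with an estimated correlation) and the 9 Schwann cell and nerve genes one of 0.59 (adjusted p = 6.28e-05; adjusted p = 0.703 with an estimated correlation). The 10 T cell genes had a median of 0.46 (adjusted p = 0.0234; adjusted p = 0.936 with an estimated correlation) and the 5 B cell genes one of 0.93 (adjusted p = 0.0473; adjusted p = 0.936 with an estimated correlation). In these lists 0 members passed when adjusted over the list alone, and the medians of the T cell, B cell and adipocyte lists were -0.05, -0.18 and -0.34 without aPDL2_large 2. The T cell and B cell lists were also not called without Prog_b2 1 (0.0705 and 0.076) or Prog_b2 3 (0.198 and 0.141). Limma called 0 of 11913 genes, with 165 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0501.

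Small and large tumors on the combination were compared to ask what separated tumors of different size within that arm (n = 2 each). Mast cell, macrophage and antigen presentation lists stood higher in the small tumors, as did adipocyte, nerve and fibroblast lists. All 7 mast cell genes rose when adjusted over the list alone, with the tryptase Tpsb2 at 3.70 ± 0.43 (list median 3.56, camera adjusted p = 6.01e-15; adjusted p = 0.399 with an estimated correlation). In the macrophage list 3 of 15 genes rose when adjusted over the list alone, with Emr1 at 54.2 ± 27.0 and 8.83 ± 4.16 FPKM and Lyz2 at a log2 change of 2.54 ± 0.48 (list median 1.79, camera adjusted p = 1.48e-08; adjusted p = 0.399 with an estimated correlation). Of 16 genes of alternative macrophage activation 5 rose when adjusted over the list alone, with Retnla at 7.56 ± 0.86 (list median 1.80, camera adjusted p = 7.22e-09; adjusted p = 0.399 with an estimated correlation). The 18 interferon gamma response genes had a median of 1.79 and the 11 MHC class II genes one of 2.03, with 0 called in either when adjusted over the list alone (camera adjusted p = 9e-08 and 4.54e-06; adjusted p = 0.403 and 0.399 with an estimated correlation). The adipocyte, Schwann cell and nerve, and fibroblast lists had medians of 2.23, 0.67 and 0.76, with 0 called when adjusted over the list alone (camera adjusted p = 4.49e-06, 0.0115 and 0.0133; adjusted p = 0.399, 0.399 and 0.403 with an estimated correlation). The fibroblast list was not called without aPDL2_small 1 or aPDL2_large 1 (0.336 and 0.0589), nor the nerve list without aPDL2_small 2 or aPDL2_large 2 (0.372 each). Limma called 0 of 11913 genes, with 946 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0884. Each single library left out gave between 3 and 9 genes.

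The resistant tumors of the batches were compared to measure how far batch 2 stood from batch 1 for the same label, where batch and any difference between the tumors cannot be told apart. Fcrls, an Fc receptor-like scavenger of macrophages, was at 55.9 ± 25.4 FPKM in Prog_b2 (n = 3) and 3.39 in Prog (n = 5; log2 change 3.73 ± 0.63, adjusted p = 0.00163). Penk rose by 3.64, the LIM protein Pdlim4 by 3.26 and Cx3cr1 by 3.12 ± 0.45. Ly86 rose by 2.68 (adjusted p = 0.0115, and 0.0583 without Prog_b2 1 or 0.063 without Prog_b2 2). Of 15 macrophage genes 2 rose, 8 when adjusted over the list alone (median 1.19, camera adjusted p = 0.00488; adjusted p = 0.995 with an estimated correlation and 0.0648 without Prog_b2 2). Esp15 (-5.30 ± 0.59, adjusted p = 1.27e-05), Prl8a9 (-4.56), Saa3 (-4.42) and S100a8 (-4.38; adjusted p = 0.00393, and 0.0542 with library weights) fell. Cxcl1 passed at -3.80 (adjusted p = 0.049), with an adjusted p from 0.0586 to 0.18 without any 1 of 6 single libraries, and of 0.166 with library weights. Of 11 neutrophil genes 4 fell, also when adjusted over the list alone (median -1.16, camera adjusted p = 0.0142; adjusted p = 0.995 with an estimated correlation and 0.112 without Prog_b2 3). Of 7 erythroid genes 3 fell, also when adjusted over the list alone, with the globin Hbb-b2 at -3.25 ± 0.59 and Alas2 at -1.87 ± 0.40 (list median -2.94, camera adjusted p = 0.0142; adjusted p = 0.995 with an estimated correlation). Braf fell by 2.93 on the log2 scale (adjusted p = 1.11e-10), and Dusp6 did not pass (0.64, adjusted p = 0.117), nor did Emr1 (1.72, adjusted p = 0.0718).

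Of 12197 genes, 1090 passed between Prog_b2 and Prog, 351 higher (32.2%) and 739 lower, and 3098 had an unadjusted p below 0.05; with size factors 53.2% of the called genes were higher. The count was 451 without Prog_b2 1, 1905 without Prog_b2 3, 712 without Prog 2 and 632 without Prog 5.

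The contrast of residual with resistant tumors was also compared between the combination arm of batch 2 and the inhibitor arm of batch 1, as the difference between aPDL2_small minus Prog_b2 and Res minus Prog. A positive value means that the gene stood higher, relative to resistant tumors, in the residual tumors of the combination arm. The aldehyde dehydrogenase Aldh1a3 differed by 6.26 ± 1.06 (adjusted p = 0.00164), Retnla by 6.04 ± 0.93 (adjusted p = 0.000853), Esp15 by 5.22 ± 0.90, Phlda2 by 5.65 (adjusted p = 0.00694, and 0.0579 without aPDL2_small 2) and Areg by 5.21 (adjusted p = 0.0175, and 0.127 without aPDL2_small 2). Esp15 was near 0 in both residual groups (0.0737 FPKM in aPDL2_small and 0.141 in Res), so its difference comes from the resistant tumors, at 91.0 FPKM in Prog and 1.57 in Prog_b2. Retnla was at 562 ± 622 FPKM in aPDL2_small and 4.65 in Res, and at 0.302 or less in the resistant groups. Aldh1a3 was at 68.3 FPKM in aPDL2_small and 3.31 in Res, and at 18.3 in Prog_b2 and 88.8 in Prog. Areg was at 100 FPKM in aPDL2_small, 80.5 in Prog_b2 and 162 in Prog. Of 23 mitotic genes 15 were higher, 21 when adjusted over the list alone (median 1.36, camera adjusted p = 6.33e-09; adjusted p = 0.527 with an estimated correlation). Of 21 MAPK output genes 9 were higher, 14 when adjusted over the list alone (median 1.55, camera adjusted p = 9.05e-06; adjusted p = 0.527 with an estimated correlation), with Ccnd1 at 2.53 ± 0.49. Both list means were lower in the residual than in the resistant tumors of each arm, by less in batch 2. The mitotic list was at 3.493 against 4.223 in batch 2 and 2.352 against 4.355 in batch 1. MAPK output was at 5.34 against 5.855 in batch 2 and 3.866 against 5.855 in batch 1. Dusp6 differed by 1.57 ± 0.39 (adjusted p = 0.0118, and 0.0697 without aPDL2_small 2) and Spry4 by 1.91 (adjusted p = 0.0232, and 0.128 without aPDL2_small 2 or 0.0765 without Prog_b2 2). Mki67 passed at 1.26 (adjusted p = 0.0489), but not in 12 of the 15 fits without a single library, where its adjusted p ranged from 0.0552 to 0.147, nor with size factors (0.0543), no filter (0.0675) or the replicate block (0.062).

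Muscle, globin and vascular genes differed the other way, largely through higher levels in Res. Acta1 was at 8.88 FPKM in aPDL2_small and 17.8 in Prog_b2, but at 163 in Res and 5.35 in Prog. Hba-a2 was at 0.00829 FPKM in aPDL2_small and 0.498 in Prog_b2, but at 272 in Res and 7.96 in Prog. The endothelial list mean was 2.458 in aPDL2_small and 2.438 in Prog_b2, but 3.636 in Res and 2.361 in Prog. Hba-a2 differed by -6.43 ± 1.44 (adjusted p = 0.00717), and the muscle genes Acta1, Ckm, Atp2a1 and Tnnc2 by -4.82, -4.73, -4.64 and -4.53, with adjusted p-values of 0.0495, 0.03, 0.0371 and 0.0308 that became 0.24, 0.164, 0.194 and 0.174 without aPDL2_small 1 and 0.157, 0.0955, 0.12 and 0.0981 without Prog_b2 2. Acta1 and Atp2a1 did not pass in 11 and 9 of the 15 fits without a single library. All 11 muscle genes were lower, also when adjusted over the list alone (median -3.95, camera adjusted p = 1.6e-06; adjusted p = 0.527 with an estimated correlation). Of 14 endothelial genes 10 were lower and 1 higher, 11 and 1 when adjusted over the list alone (median -1.74, camera adjusted p = 4.28e-07; adjusted p = 0.527 with an estimated correlation). Of 12197 genes, 2124 passed, 1152 higher and 972 lower, and 4233 had an unadjusted p below 0.05. The count was 598 without aPDL2_small 2 and 1186 without Prog_b2 2, and the groups of the arms lie in different batches throughout.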

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

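The criteria for single tumors that stand apart and for effects that differ between batches were fixed before the data were examined, while the tests of explanations named at the end were chosen only after the result was seen.

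By Dixon's test, 19 of 264 groups of values held a tumor far from the rest, where chance alone gives about 1 in 20. Among single genes, S100a9 was at 85.6 FPKM in Veh 1, Ibsp at 0.235 in Veh 2 (the lowest of its group), Ccnd1 at 339 in Reg 1, Esp15 at 0.938 and Ibsp at 5.88 in Reg 1. Cd274 was at 20.5 FPKM in Reg 3 and 18.6 in Res 4, Dct at 0.244 in Reg 2, Mki67 at 6.82 in Res 1, Dusp6 at 74.2 in Res 5 and Saa3 at 463 in Prog 2.

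Among list means on the log2 scale, the neutrophil list was at 2.33 in Veh 1, the adipocyte list at 3.28 in Veh 3 and the pericyte and smooth muscle list at 2.12 in Reg 1 (the lowest of its group). The keratinocyte list was at 4.85 and the mitotic list at 2.87 in Res 1. In the resistant tumors the B cell list was at 0.26 in Prog 4, and the MAPK output and immediate early lists were at 6.11 and 5.28 in Prog 3.

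The residual-to-resistant contrast differed between the combination arm of batch 2 and the inhibitor arm of batch 1 for 2124 genes. The named genes were Aldh1a3 (6.26), Retnla (6.04), Phlda2 (5.65), Esp15 (5.22), Areg (5.21), Spry4 (1.91), Dusp6 (1.57) and Mki67 (1.26) on the higher side, and Hba-a2 (-6.43), Acta1 (-4.82), Ckm (-4.73), Atp2a1 (-4.64) and Tnnc2 (-4.53) on the lower side. Lists with a higher median were adipocyte (3.32), MAPK output (1.55), hypoxia and glycolysis (1.42), mitotic (1.36) and DNA replication (1.01). With an estimated correlation 0 of these lists was called, with adjusted p = 0.599 for hypoxia and glycolysis and 0.527 for the others. Lists with a lower median were skeletal muscle (-3.95), erythroid (-2.01), macrophage (-1.83), endothelial (-1.74), neutrophil (-1.73), myeloid chemokines (-1.09) and pericyte and smooth muscle (-0.92). Here too 0 was called with an estimated correlation (adjusted p = 0.828 for macrophage and 0.527 for the others). Without aPDL2_small 2 the macrophage and myeloid chemokine lists were not called (0.269 and 0.0506), and without aPDL2_small 1 the erythroid and pericyte lists were not (0.054 and 0.188). Without Prog_b2 2 the chemokine and pericyte lists were not called (0.0755 and 0.0934), nor without Res 5 (0.0668 each), and the erythroid list was not without Res 3 (0.0692). The pericyte list was also not called without Prog_b2 3, Res 2, Prog 3 or Prog 4 (0.0539, 0.0575, 0.0506 and 0.0661).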

How the results depend on the processing

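The settings without Veh 1, Veh 3 and Res 1, with a term for columns that look like means and with exact permutation of list means were chosen only after the result was seen; the others were planned. The cause of the differences was not tested.

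With an estimated correlation, camera called 0 lists in all 10 comparisons, where the preset correlation gave 20, 17, 15, 12, 19, 21, 4, 23, 4 and 12. By fry the counts were 0 for Reg vs Veh, 21 for Res vs Veh, 8 for Prog vs Veh, 12 for Res vs Reg, 26 for Prog vs Res, 2 for aPDL2_small vs Prog_b2, 0 for aPDL2_large vs Prog_b2, 0 for aPDL2_small vs aPDL2_large 0 for Prog_b2 vs Prog and 12 for the difference between the contrasts. Exact permutation of list means called 0 lists for Reg vs Veh, 8 for Res vs Veh and 0 for Prog vs Veh. For Res vs Reg, Prog vs Res and Prog_b2 vs Prog it called 0, 30 and 0. The smallest p-values that 4 against 4, 5 against 5 or 4, and 3 against 5 tumors gave were 0.0286, 0.00794 and 0.0179. After adjustment over 37 or 38 lists, a list at these values passes only if enough others reach them too. In Prog vs Veh the lists at 0.00794 had an adjusted exact p of 0.0588. A count of 0 therefore does not show that no list changed.

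Gene counts for Reg vs Veh went from 2 to 31 with library weights. For aPDL2_small vs Prog_b2 they went from 0 to 17 with no filter, 598 with all 25 libraries in 1 fit and 5 with only the compared groups. For aPDL2_large vs Prog_b2 they were 1 with no filter, 1 with weights and 2 with all libraries, and for aPDL2_small vs aPDL2_large 1, 3 and 34. For Prog_b2 vs Prog, 1090 became 495 with the replicate block and 631 with weights. With the block, 14 lists were called for aPDL2_large vs Prog_b2, against 4.

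With the resistant tumors of batch 2 in place of batch 1, 2014 genes differed from Veh, against 5658. The log2 changes of Mmp9 (-0.714), C1qa (0.124), Nrg1 (-0.135), Cxcr2 (-0.121), Mmp8 (-0.112) and Emr1 (0.192) then had the opposite sign.

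In aPDL2_large vs Prog_b2 several list medians turned. The block, and leaving out Prog_b2 3, gave 0.225 for the mitotic list, 0.247 for DNA replication and -1.016 for MHC class II. Without aPDL2_large 1 the endothelial list was at 0.242, against -0.378 without aPDL2_large 2; skeletal muscle was at -1.08 and MHC class II at 0.992 without aPDL2_large 1. Without aPDL2_large 2 the T cell, B cell and adipocyte lists were at -0.052, -0.185 and -0.342, against 1.21, 1.90 and 2.67 without aPDL2_large 1. Without Prog_b2 2 the skeletal muscle, interferon gamma, type I interferon and MHC class I lists were at 0.948, 0.554, 0.644 and 0.684, and the mitotic and DNA replication lists at -0.504 and -0.216. Without Prog_b2 3 the interferon gamma, type I interferon and MHC class I lists were at -0.89, -1.25 and -0.585.

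With Veh libraries split between the comparisons, Res and Prog shared 618, 645, 541, 580, 544 and 584 genes in 1 direction, against 1079. With Veh 3 and 4 kept for Reg, Reg shared 55 genes with Res and 15 with Prog.

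Single libraries mattered most in batch 2, where a group left with 1 library is assumed to vary like the others. Gene counts reached 16 for aPDL2_small vs Prog_b2 without aPDL2_small 2, 3 for aPDL2_large vs Prog_b2 without aPDL2_large 1 and 9 for aPDL2_small vs aPDL2_large without aPDL2_small 2. For Prog_b2 vs Prog they ran from 451 without Prog_b2 1 to 1905 without Prog_b2 3, and for the difference between the contrasts from 598 without aPDL2_small 2 to 2858 without Res 5. In batch 1 they ran from 2 to 5 for Reg vs Veh (5 without Veh 1), from 4468 to 6173 for Res vs Veh, from 4735 to 5580 for Prog vs Veh, from 3320 to 5091 for Res vs Reg and from 8389 to 8968 for Prog vs Res. List counts were 9 for Reg vs Veh without Veh 3, 9 for Prog vs Veh without Prog 3 (5 higher, 4 lower) and 9 without Veh 4 (2 higher, 7 lower), against 6 higher and 9 lower, 13 for aPDL2_large vs Prog_b2 without Prog_b2 2, 22 and 15 for aPDL2_small vs aPDL2_large without aPDL2_small 1 and 2, and 9 for Prog_b2 vs Prog without Prog_b2 3.

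Without Veh 1, Veh 3 and Res 1 the gene counts were 4106 for Res vs Veh and 4340 for Prog vs Veh. With the term for columns that look like means they were 5517 and 5645. Replicate numbers did not pair tumors across groups, since correlations of numbered pairs in batch 1 ran from -0.517 to 0.374.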

Other observations

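All tests of explanations in this part were chosen only after the result was seen.

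Of 26 prolactin family genes in the table, chosen after their values were seen, 5 passed the expression filter in batch 1 (Prl2a1, Prl2c2, Prl2c3, Prl6a1 and Prl8a9). Their median log2 change was 4.38 in Prog vs Veh and -0.01 in Res vs Veh. Because levels in Prog helped these genes pass the filter, and no test of the family was run, nothing follows for the family as a whole.

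The higher Braf in the resistant tumors of batch 1 may come from a gain of copies of its region, because the 14 tested neighbours of Braf had a median log2 change of 1.813 in Prog vs Veh. Among 11235 windows scanned along the genome, 0 away from Braf reached that value, and the highest of these, at Osbpl5 on chromosome 7, was 1.403. Reads shared with a copy of Braf elsewhere would leave the neighbours unchanged, yet 10 of 14 were called higher. Processing of batch 1 as a whole would raise Braf in all its libraries, but the lowest Braf level in Prog was 4.35 times the highest in the other tumors of batch 1. Braf was chosen for this pattern, so the ratio restates it and is no separate test. In Prog_b2 the median of the same neighbours differed from Veh by 0.083, and DNA copy number was not analysed here.

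The mitotic list mean on the log2 FPKM scale fell in Res by 2.882 ± 0.184 against Veh (two-sided exact p = 0.00794, the smallest that 126 splits can give). A lower share of tumor cells alone would raise the lists of all host cells roughly alike. The change of the neutrophil list mean exceeded that of the endothelial list by 2.398 ± 0.397. The endothelial, fibroblast and pericyte list means rose by 0.949, 1.036 and 1.054, close to each other, and the T cell list by 0.896. The macrophage, mast cell and neutrophil lists rose by 1.673, 2.581 and 3.347, and the keratinocyte list changed by -1.076. The pair compared was picked after its values were seen and starts from unlike levels in Veh (1.618 and 2.687). It therefore does not decide on a lower share. Nor does it measure how much of the mitotic fall a lower share explains. The Y-linked genes Ddx3y, Kdm5d and Uty changed by -0.693 ± 0.649 in Res against Veh (two-sided exact p = 0.357). If host cells lack these genes, their smaller fall argues against a lower share as the whole cause. The labels do not give the sex of the mice, but Eif2s3y, another Y-linked gene, was at most 0.0252 FPKM in all 18 libraries of batch 1. Host cells with Y-linked expression would bring Eif2s3y too. The values therefore argue against a lower share as the whole cause of the mitotic fall. A lower share as a part of the cause, with or without an influx of neutrophils, stays open. With median-of-ratios size factors the median mitotic change was -2.51 and all 23 genes were called. These factors lay between 0.942 and 1.059, too close to each other to move a fall of this size much, so this hardly tests the scaling of the FPKM. With the muscle list mean as a covariate the median mitotic change was -2.03, again with 23 called. The muscle list itself went to 0.014, which follows from using its own mean as the covariate.

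Xist and Eif2s3y, chosen after their values were seen, split the batches: Xist ranged from 0.688 to 13.7 FPKM in batch 1 and from 0.00552 to 0.0223 in batch 2, and Eif2s3y from 0 to 0.0252 and from 1.21 to 10.2. Host mice of different sex are a possible explanation: Xist followed the macrophage list within batch 1 (group-centred, n = 18, r = 0.956, two-sided permutation p = 4e-05, adjusted 0.00032; rho = 0.88, permutation p = 2e-04, adjusted 0.0016; r = 0.912 without the 2 farthest tumors), and Eif2s3y rose with it across batch 2 by r alone (not centred on groups, so the higher macrophage list of aPDL2_small enters; n = 7, r = 0.933, permutation p = 0.00159, adjusted 0.00533; rho = 0.857, permutation p = 0.0238, adjusted 0.0635; r = 0.848 without the 2 farthest), with p adjusted over 8 relations. The other host lists were mixed and leave this open: Xist followed the T cell list (r = 0.721, permutation p = 0.002, adjusted 0.00533; rho = 0.74, p = 0.002, adjusted 0.008; r = 0.62 without 2) but not the endothelial (r = 0.437, permutation p = 0.2, adjusted 0.229; rho = 0.389, p = 0.2, adjusted 0.229; r = 0.24 without 2) or fibroblast list (r = 0.334, permutation p = 0.2, adjusted 0.229; rho = 0.325, p = 0.2, adjusted 0.229; r = 0.2 without 2), and for Eif2s3y the endothelial (r = 0.485, permutation p = 0.28, adjusted 0.28; rho = 0.464, p = 0.302, adjusted 0.302; r = 0.172 without 2), T cell (r = 0.776, permutation p = 0.0274, adjusted 0.0548; rho = 0.821, p = 0.0341, adjusted 0.0682; r = 0.935 without 2) and fibroblast lists (r = 0.744, permutation p = 0.0431, adjusted 0.069; rho = 0.75, p = 0.0663, adjusted 0.106; r = 0.938 without 2) did not pass. Annotation that differed between batches would split many genes, but only 2 differed by more than 10-fold throughout. Loss of the Y chromosome from the tumor cells of batch 1 would remove Ddx3y, whose lowest level there was 3.22 FPKM.

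Other splits of the same libraries into groups of the same sizes were run for each comparison with enough of them. For gene counts, Reg vs Veh was reached by 2 of 35 splits including the real one (highest other 3), so chance is not excluded for its 2 genes. For Res vs Veh and Res vs Reg, 2 of 100 splits were as large, the other having Res 5 with the comparison group (5635 and 4589 genes). For Prog vs Veh, Prog vs Res and Prog_b2 vs Prog only the real split was, with 4167, 5692 and 78 genes in the next. For the number of lists called, as many or more came from 4 of 35 splits for Reg vs Veh (20 lists, highest other 22), 52 of 100 for Res vs Veh (17, 24), 24 of 100 for Prog vs Veh (15, 22), 73 of 100 for Res vs Reg (12, 25), 22 of 100 for Prog vs Res (19, 21) and 50 of 56 for Prog_b2 vs Prog (4, 12), so chance is not excluded for these numbers. Other splits called a median of 13 lists for Reg vs Veh, 17 for Res vs Veh, 8 for Prog vs Veh and 15 for Res vs Reg. For Prog vs Res and Prog_b2 vs Prog the medians were 15 and 7. Camera with the preset correlation thus called many lists in groups that do not follow the labels. Such splits can hold part of a real difference, but a camera adjusted p below 0.05 alone is weak support for a single list. Exact permutation of list means passed 30 of 37 lists for Prog vs Res and 8 of 37 for Res vs Veh after adjustment. That threshold bounds the expected share of false calls, so it does not exclude chance for each list. The 5 higher in Res were macrophage, neutrophil, fibroblast, pericyte and smooth muscle, and myeloid chemokines. The 3 lower were mitotic, DNA replication and oxidative phosphorylation. Skeletal muscle, erythroid and endothelial (adjusted exact p = 0.0518 each), MAPK output and checkpoint (0.098 each) did not pass. For the other comparisons of batch 1 and for Prog_b2 vs Prog 0 passed. The unadjusted exact p was below 0.05 for 2 (Reg vs Veh), 14 (Prog vs Veh), 13 (Res vs Reg) and 5 (Prog_b2 vs Prog) lists.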
